A study of Sus scrofa with 4 samples.

How the data were processed

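Adipose tissue of male Erhualian pigs was profiled by rRNA-depleted, strand-specific RNA sequencing. Per the labels' protocols, total RNA of 3 animals was pooled in equal parts for each of 4 depots (intramuscular IAT, subcutaneous SAT, retroperitoneal RPAT and mesenteric MAT), ribosomal RNA was removed, and 1 library per depot was made with a directional kit and read on an Illumina HiSeq X instrument. Groups were taken from the tissue label of each library. The pools leave no replicate of any depot, so no test between depots was possible and no p-value is given.

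The deposited tables hold the same 49419 rows in every library. Per the file headers, FPKM (fragments per kilobase of exon and 1000000 mapped fragments) is the unit deposited for genes and long noncoding RNAs (lncRNAs), and SRPBM (spliced reads per 1000000000 mapped reads) is the unit deposited for 13746 circular RNAs (circRNAs), RNA loops recognised by a back-spliced junction. The submitters' processing notes name HISAT2 2.0.5 and BWA, with no role given. The read counter, the circRNA caller, the annotation release and the strand setting of the counting are not given in the sources used here. Antisense rows are therefore reported as uncertain, as are rows that overlap another gene. Names, gene class and position were used as deposited. Of 19168 protein-coding rows with a unique symbol match on the chromosomes of the Sscrofa11.1 RefSeq gene table, 19055 had the same chromosome, start and end (99.4%), and positions are given on that build, counted from 1. Rows named LOC or rna, 3768 of the 20193 protein-coding rows, and 26 rows whose name a spreadsheet had turned into a date were treated as having no symbol.

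Both units keep whole reads. All SRPBM values of a library were multiples of the worth of 1 back-spliced read (6.41 to 9.71 SRPBM), with a largest distance of 0.000304 from a whole number, and no circRNA was listed with fewer than 2 reads. In units of 1000000, these steps correspond to 139 mapped reads in IAT, 156 in SAT, 103 in RPAT and 144 in MAT. The denominators of FPKM were found from the miRNA rows, where 100% of the values above 0 (110 to 155 per library) came within 0.01 of a whole number of reads: 47684263 in IAT, 56075577 in SAT, 32644520 in RPAT and 57201834 in MAT. For every gene, the shortest length that gave whole reads in all 4 libraries was then taken, and the recovered reads summed to 98.6% to 98.8% of these denominators. Reads found this way are a minimum, since the true number can be a multiple, above all for rows seen in 1 or 2 libraries. Fold intervals are exact 95% intervals of a ratio of Poisson rates on these reads, and shares have exact Clopper-Pearson intervals. Reads carry no molecular identifiers, so intervals and the floor of 3 reads for a 0 cover counting error only and say nothing about animals.

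Calls were made by size, on rules fixed before the data were examined. A protein-coding gene was called higher in a depot when its log2(FPKM + 1) lay at least 1 above that of each of the other 3 libraries, and lower when it lay at least 1 below each, with a highest value of at least 1 FPKM. The pseudocount of 1 understates differences of weakly expressed genes. The same rule with a minimum of 0.5 FPKM was used for lncRNA rows. The 6 pairs of libraries were compared with the same threshold and by Spearman's rho and Pearson's r across genes, which are not independent replicates. A circRNA was called higher in a depot when its SRPBM was at least 2 times that of each other library and it had at least 10 reads there. A circRNA was assigned to the gene that spans both of its ends on the same strand, and across circRNAs with at least 10 reads in total its difference was set against that of its host by Spearman's rho.

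Gene lists, 41 in number, were fixed beforehand for cell types that dissected fat could hold, metabolic and signalling pathways, positional transcription factors, reference genes and noncoding RNAs. For each, the median log2(FPKM + 1) difference between a depot and the mean of the other 3 libraries was set against 10000 random lists of the same size matched on mean expression within 100 ranks, and a list was called high or low when it lay outside the middle 95% of them. SAT was also set against the mean of RPAT and MAT. Genes of a list are often controlled together, so these percentiles describe the libraries and are not p-values. Of the lists, 35 had at least 4 detected genes, and 74 of their 140 combinations with a depot lay outside, where 5% would by the choice of percentiles. The genes named were fixed by rule: per depot the 12 highest and 8 lowest by the smallest of the 3 differences, with a symbol and at least 5 FPKM; the 5 most abundant per library; up to 4 members of called lists; ADIPOQ, LEP, PPARG, FASN, SCD, ACTA1 and CKM; 3 lncRNAs per depot; and the 5 most abundant circRNAs with 3 more per depot. Some genes that met these rules are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

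The steps were tested on simulated data, with Poisson reads drawn for 20189 protein-coding rows at the real means and library sizes and 200 genes raised in MAT alone. The rule called 0 of 50 genes raised 1.5-fold, 36 of 50 raised 2.5-fold, 50 of 50 raised 4-fold and 50 of 50 raised 8-fold, and made 1 call in any depot and direction among 11213 unchanged genes. Reads were recovered exactly for 1422 of 1500 simulated genes (94.8%). These genes were simulated at the lengths already recovered and had reads in every library. Recovery was therefore not tested where the true length is a multiple or where some libraries have no reads. With no change simulated, the lncRNA rule made 4 to 8 higher calls per depot among 4133 rows, and the circRNA rule 14 to 21 per depot among 13746. Of 100 random lists of 15 unchanged genes, 2 fell outside the percentiles in MAT.

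Alternatives fixed beforehand were another pseudocount, other minimum values, a threshold of 2 log2 units, rescaling by the median ratio or to 1000000 per library (TPM), the mean of a list, and other read minimums, folds and denominators for circRNAs. Recomputing the comparisons without the IAT library was added after seeing the data, because that library alone holds high levels of muscle fibre genes. Median-ratio rescaling shifted MAT by -0.13 log2 units against the mean of the others, and TPM shifted IAT by 0.17 and MAT by -0.12, so differences of that size depend on the scaling. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.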

Results

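The series asked how messenger RNAs, lncRNAs and circRNAs differ among 4 fat depots of the pig. IAT lies between muscle fibres, SAT under the skin, RPAT behind the abdominal cavity and MAT in the mesentery that carries the intestine. Each depot is represented by 1 library made from the pooled RNA of 3 male pigs, so no difference below has a replicate check, and the intervals given cover counting error alone. The libraries held 47684263 (IAT), 56075577 (SAT), 32644520 (RPAT) and 57201834 (MAT) reads in the FPKM denominators, at which 3 reads on 1 kb of transcript correspond to 0.0629, 0.0535, 0.0919 and 0.0524 FPKM. Between 10773 (SAT) and 11309 (IAT) protein-coding genes reached 1 FPKM. The 5 most abundant messenger RNAs in SAT and RPAT were those of fat synthesis and the fat cell with, in second place, the elongation factor EEF1A1 (4445 and 4790 FPKM). In SAT, SCD, the desaturase of newly made fatty acids, reached 6049 FPKM. In RPAT, FABP4, the fatty acid carrier of adipocytes, reached 5029 FPKM. In MAT EEF1A1 came first (5345 FPKM), followed by FABP4 (5259 FPKM), and in IAT the fast-muscle troponin TNNC2 came first (8196 FPKM).

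IAT stood apart from the other depots. Spearman's rho across genes was 0.930 to 0.932 between IAT and the other libraries and 0.956 to 0.965 among SAT, RPAT and MAT. Of 12146 protein-coding genes considered, 541 were higher and 312 lower in IAT than in each other library, against 35 and 31 in SAT, 21 and 3 in RPAT, and 99 and 10 in MAT. With a pseudocount of 0.1, which admits more rows of few reads, the split turned in SAT (62 higher and 132 lower) and RPAT (39 and 59). With values rescaled to TPM the split in IAT was 677 higher and 214 lower. By pairs, 907 genes were higher in IAT than in SAT and 646 lower, 960 higher and 815 lower than in RPAT, and 706 higher and 691 lower than in MAT. Under TPM these splits were 1116 and 503, 1194 and 648, and 912 and 477. Among the remaining pairs SAT and RPAT were nearest by this count, with 148 genes higher in SAT and 129 higher in RPAT. With a pseudocount of 0.1 the order turned, with 647 genes apart between SAT and RPAT and 638 between RPAT and MAT. Between RPAT and MAT, 106 were higher in RPAT and 195 in MAT. Between SAT and MAT, 200 were higher in SAT and 418 in MAT, or 260 and 318 after median-ratio rescaling.

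**Figure D1:**
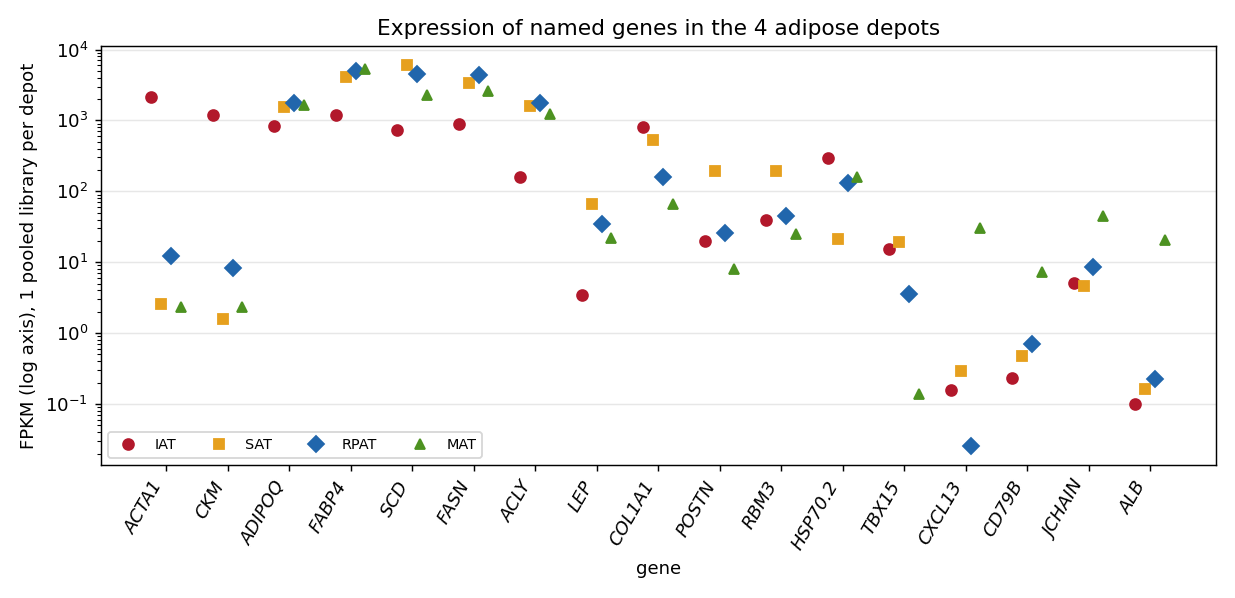
FPKM of 17 genes on a log axis, with 1 point for each pooled library (IAT, SAT, RPAT and MAT) and no error bars because there are no replicates. ACTA1 and CKM are high in IAT alone (2127 and 1207 FPKM), LEP is lowest there (3.41 FPKM), RBM3 is highest in SAT (195 FPKM), and CXCL13 and ALB are high in MAT alone (30.3 and 20.3 FPKM).

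Genes of the skeletal muscle fibre separated IAT from the other depots. All 31 detected genes of the muscle fibre list were higher in IAT than in each other library, with a median difference of 7.34 log2 units from the mean of the others (100th percentile). They took 7.80% of the reads in IAT, 0.0130% in SAT, 0.0504% in RPAT and 0.0120% in MAT. The 12 genes with the largest differences mostly code for proteins of the contractile apparatus, calcium handling or muscle energy supply. The fast troponin subunits TNNI2 (chromosome 2: 1251566 to 1253883) and TNNC2 (chromosome 17: 48025621 to 48026762) were 193-fold (172 to 216) and 167-fold (156 to 180) above RPAT, the nearest library. The myosin light chain MYLPF was 184-fold above it (169 to 200), skeletal actin ACTA1 176-fold (164 to 189) and creatine kinase CKM 144-fold (133 to 155). MYL1 (2920 FPKM), the muscle enolase ENO3 (1527), COX8H (623), the calcium pump regulator SLN (609), TNNT3 (551), MYOZ1 (452) and KLHL41 (444) completed the 12. The myogenic regulators MYF6 (61.0 FPKM), MYOG (14.1) and MYOD1 (2.25) were the detected members of the satellite cell list, too few for a percentile.

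Other lists were high in IAT beside the muscle genes. Lymphatic endothelium had a median difference of 2.33 (100th percentile), with 4 of 7 genes higher than in each other library; the chemokine CCL21 reached 31.3 FPKM against 0.772 to 3.38 elsewhere, and MMRN1 21.9 against 1.52 to 3.40. Smooth muscle and pericyte genes had a median of 1.71 (100th percentile), 7 of 13 higher, with smooth muscle actin ACTA2 at 558 FPKM against 32.0 to 71.4. That list also holds DES and SYNM, which skeletal muscle expresses. Peripheral nerve genes had a median of 1.13 with 6 of 11 genes higher than in each other library. Collagen and matrix genes had a median of 1.04, and COL1A1 reached 809 FPKM in IAT, 526 in SAT, 161 in RPAT and 66.0 in MAT. Glycolysis had a median of 0.99, with 9 of 18 genes higher and 2 lower; the higher ones included the muscle forms ENO3, PGAM2 and PFKM. The mesothelium list, at 2.80, rested on the keratins KRT8 (42.8 FPKM), KRT19 (17.7) and KRT18 (10.7), which many epithelia share. Blood vessel endothelium, at -0.07, lay at the 59.2nd percentile.

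Genes of the adipocyte and of fat synthesis were lower in IAT. The mature adipocyte list had a median of -1.42 (percentile 0) with 10 of 19 genes lower than in each other library and 0 higher, and the fatty acid and triglyceride synthesis list a median of -1.52 (percentile 0) with 15 of 22 lower and 1, ACACB, higher. ACLY, which makes the acetyl-CoA for fatty acids, stood at 160 FPKM in IAT, 7.74-fold below MAT (7.66 to 7.83), and at 1237 to 1785 elsewhere. THRSP, a regulator of lipogenesis, stood at 628 against 3477 to 4506 FPKM. FASN, the fatty acid synthase, was 2.96-fold below MAT (2.95 to 2.97), and SCD 3.09-fold (3.07 to 3.10). The hormone leptin (LEP) was 6.42-fold below MAT (5.97 to 6.92), with 3.41 FPKM in IAT, 66.6 in SAT, 34.7 in RPAT and 21.9 in MAT. ADIPOQ, which codes for adiponectin, differed less (825 FPKM in IAT and 1538 to 1767 elsewhere), as did PPARG, the main regulator of adipocyte identity (19.6 against 25.3 to 45.4 FPKM). Outside these lists, genes far lower in IAT included CLPSL2, MMD, APOE (207 against 1226 to 1459 FPKM) and ADAMTS18. Lipolysis (-1.09), fatty acid uptake (-0.74) and fatty acid oxidation (-0.66) were low as well, at percentiles 0, 1.1 and 0.45. The B cell (-0.73) and T cell (-0.65) lists lay low against a mean that includes the high values of MAT, and 0 of 10 and 0 of 13 of their genes were lower in IAT than in each other library.

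**Figure D2:**
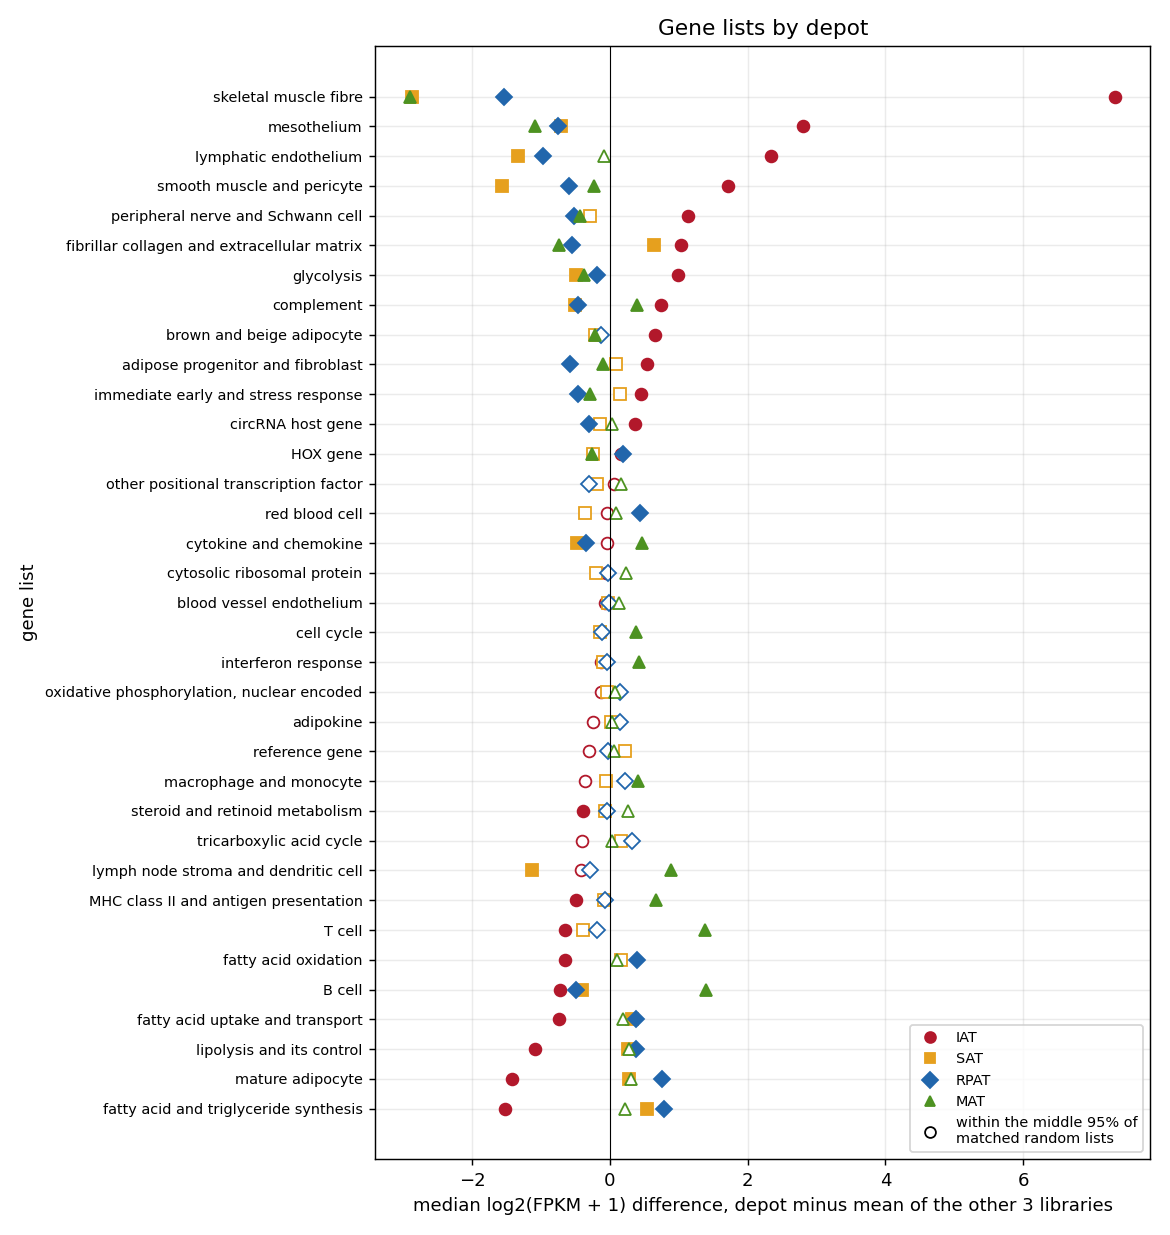
Median log2(FPKM + 1) difference of each depot from the mean of the other 3 libraries for the 35 gene lists with at least 4 detected genes. Filled symbols lie outside the middle 95% of 10000 matched random lists; muscle fibre genes reach 7.34 in IAT, and B cell and T cell genes both reach 1.39 in MAT.

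SAT was marked by a few higher genes, among them a matrix protein and a cold-inducible RNA-binding protein, and by low heat shock genes. Its 35 higher genes were led by CRYM, a thyroid hormone binding protein (19.9 FPKM against 0.769 to 1.22 elsewhere), and by POSTN (chromosome 11: 13225183 to 13258973), which codes for the matrix protein periostin, at 193 FPKM and 7.46-fold above RPAT (7.19 to 7.76). HTRA4 was 5.24-fold above RPAT (4.85 to 5.67) and RBM3, an RNA-binding protein induced by mild cold, 4.31-fold (4.10 to 4.53). FOSB was 3.69-fold above MAT (3.54 to 3.85). SAL1, SMIM10, FCN2, OLFML2A, SLITRK6 and FBLN7 followed, at 2.63-fold to 3.45-fold above the nearest library. Among the 31 lower genes was the chaperone HSP70.2, at 21.5 FPKM and 6.12-fold below RPAT (5.85 to 6.41). The chaperone HSPA6, at 0.871 FPKM and 7.54-fold below RPAT (6.19 to 9.25), was lower too, with the partners STIP1 and DNAJA1. UNC45B was also among them, at 0.388 FPKM in SAT, 3.13 in RPAT and 3.01 in MAT. It was highest in IAT (28.6), as muscle fibre genes were. The heat shock genes have near-identical copies, so reads may be split among them. The complement component C7 (2.48 FPKM against 10.2 to 29.7), the fibroblast gene PI16 (12.9 against 39.5 to 167) and HMCN1 were lower too.

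Against the mean of RPAT and MAT, collagen and matrix genes were higher in SAT by a median of 0.88 log2 units (100th percentile), with 22 of 24 above 0 and 8 above both depots by the rule. COL1A2 stood at 953 FPKM in SAT, 334 in RPAT and 221 in MAT, and COL6A3 at 166, 60.2 and 44.2. Against all other depots the list was higher in IAT (1.04) than in SAT (0.65), and of its genes POSTN alone was higher in SAT than in each other library. Progenitor and fibroblast genes had a median of 0.30 (100th percentile) but went both ways, with 9 of 14 above 0 and a mean of 0.094. Lymph node stroma and dendritic cell genes were lower (-1.14, percentile 0), as were B cell and T cell genes (both -0.68). The mean here includes the high values of MAT, and 0 genes of these lists were lower in SAT than in both depots. Smooth muscle genes were lower too (-0.60). The immediate early and stress list was higher (0.47, 100th percentile), with FOS at 324 FPKM against 158 in RPAT and 196 in MAT, and EGR1 at 19.8 against 7.42 and 10.1. Its heat shock members DNAJB1, HSPH1 and HSPA6 went the other way. The mature adipocyte list did not stand apart between SAT and these depots (-0.19, 27.2nd percentile), although LEP was highest and SCD was 1.34-fold above RPAT (1.33 to 1.34). Without the IAT library, 90 genes were higher and 58 lower in SAT than in both RPAT and MAT.

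RPAT had the fewest genes of its own. NEMF, a factor of ribosome quality control (chromosome 1: 179622728 to 179671225), was 10.1-fold above MAT (9.82 to 10.5), at 139 FPKM against 11.8 to 13.7. The neutrophil genes NPG4 (5.12 against 0.0337 to 0.317 FPKM), S100A8 (57.3 against 7.12 to 18.4) and S100A9 (30.2 against 4.28 to 12.3) were higher, as were IL23A, the transcription factor DMRT2 and AKR1CL1 (648 against 105 to 318). The red blood cell list was high as well (0.44, 98.4th percentile, 4 of 4 genes above 0), though inside the middle 95% with a pseudocount of 0.1. PI15 and C4A were among the 3 lower genes, and C4A shares most of its sequence with other complement C4 copies. The adipocyte and synthesis lists had medians of 0.76 and 0.79 (both 100th percentile). Set against SAT and MAT alone they were 0.29 and 0.30, at the 100th percentile again. FASN was 1.27-fold above SAT (1.26 to 1.27), whereas SCD was 0.75-fold of SAT (0.747 to 0.750). Progenitor and fibroblast genes were low (-0.59, percentile 0), with 0 of 14 above 0. The HOX list was high (0.19, 99.6th percentile), with HOXA9 at 1.69 FPKM against at most 0.298. Muscle fibre genes, though far below IAT, lay 1.47 log2 units above the mean of SAT and MAT (ACTA1 12.1 against 2.60 and 2.37 FPKM). Without IAT, 40 genes were higher and 7 lower in RPAT.

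MAT was marked by lymphoid genes and by plasma protein genes of the liver. CXCL13, the chemokine that draws B cells (chromosome 8: 73071261 to 73077342), was 102-fold above SAT (66.1 to 168), at 30.3 FPKM. Genes of the B cell receptor and of antibody-secreting cells were higher too. CD79B was 10.3-fold (7.39 to 14.9), CD79A 7.03-fold (4.94 to 10.3) and JCHAIN 5.27-fold (4.75 to 5.86) above the nearest library. CD69, an early activation marker of lymphocytes, was 8.54-fold (5.93 to 12.7) and the interferon-induced chemokine CXCL9 4.90-fold above (3.22 to 7.71). Albumin (ALB) stood at 20.3 FPKM against 0.0997 to 0.224, the fibrinogen chains FGB, FGA and FGG at 9.40, 8.96 and 6.25 FPKM against at most 0.337, and haptoglobin (HP) at 22.1 against 0.631 to 2.93. GREM1, an antagonist of bone morphogenetic proteins, was 16.8-fold above RPAT (14.4 to 19.6). In the lists, B cell genes had a median of 1.39, with 10 of 10 above 0 and 5 higher than in each other library, and T cell genes a median of 1.39, with 13 of 13 above 0 and 7 higher. Antigen presentation (0.67), lymph node stroma (0.89), cytokines (0.47), interferon response (0.42), macrophages (0.40), complement (0.40) and cell cycle (0.38) also lay above the middle 95% of the random lists. Among lymph node stroma genes CCL19 reached 286 FPKM against 51.4 to 75.2.

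A gene of body position and genes of the matrix were lower in MAT. TBX15 (chromosome 4: 101918891 to 102032280), a transcription factor of the body wall and limb, stood at 0.137 FPKM in MAT, 3.60 in RPAT, 15.2 in IAT and 19.1 in SAT, and was 26.2-fold below RPAT (18.7 to 37.9). SFRP4, COL1A1, COL5A1 and POSTN were 2.81-fold, 2.44-fold, 2.09-fold and 2.47-fold below the nearest library. The collagen and matrix list had a median of -0.73 (percentile 0), with 1 of 24 genes above 0. Without IAT, 147 genes were higher and 31 lower in MAT, and smooth muscle genes, lower in MAT against all others (-0.24), were higher against SAT and RPAT (0.67, 100th percentile).

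Among lncRNAs, IAT again had the most. Of 5993 rows of at least 0.5 FPKM, 109 were higher and 34 lower in IAT, 34 and 6 in SAT, 60 and 0 in RPAT, and 21 and 2 in MAT. RPAT was the shallowest library, and rows of few reads vary most there. Counting error alone, simulated without change on 4133 rows, gave 8 higher calls in RPAT and 4 to 7 in the other depots. The leading IAT rows were LOC110257453 (357 FPKM against at most 2.43), LOC106505720 (52.6 against at most 0.586) and MSTRG.566759 (64.1 against at most 1.22). The first overlaps TNNC2 and the third TTN on the opposite strand, and with the strand setting of the counting not given, their reads cannot be told from those of the muscle genes. In SAT the leading rows were LOC106505688 (3.21 FPKM), MSTRG.587638 (3.41) and LOC106505255 (13.2). In RPAT they were LOC110256939 (8.01 FPKM, opposite FARSB), LOC110261988 (4.99, opposite ELOVL6) and MSTRG.512186 (1.92, listed at 0 elsewhere). The number of reads of MSTRG.512186 could not be recovered with confidence. At the minimum of 2 reads its fold interval starts at 0.274, so counting error alone could give this difference. In MAT they were MSTRG.674749 (6.17 FPKM, opposite LOC100038328 and LOC110258830), MSTRG.665241 (2.80) and MSTRG.665240 (2.15), the last 2 opposite each other on an unplaced contig. All rows opposite another gene are uncertain in this way. The counts are sensitive to the pseudocount, and with 0.1 FPKM the IAT-high rows numbered 809.

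CircRNAs were most abundant in IAT and MAT. IAT held 7791 detected circRNAs and 725828 SRPBM in sum, MAT 6968 and 656288, RPAT 5005 and 433222, and SAT 4356 and 322735. Of the 13746, 7995 were found in 1 library, 7283 of these with fewer than 10 reads, and 1447 in all 4. The most abundant circRNA, ssc_circ_0001439, came from ME1 (chromosome 1: 82875117 to 82891579), the gene of malic enzyme, which supplies NADPH for fat synthesis. It reached 51675 SRPBM in MAT, 39700 in RPAT, 26758 in SAT and 8608 in IAT, and was 1.93-fold higher in MAT than in SAT (1.86 to 2.01). Its host messenger RNA ran in another order, with 591 FPKM in SAT, 509 in RPAT, 436 in MAT and 91.8 in IAT. The sum of all circRNAs also rose from 322735 SRPBM in SAT to 656288 in MAT, so the circle did not rise more than circRNAs as a whole. The order of the circle against its host was not corrected for these totals. Circles from PHF21A (577 SRPBM in SAT and 1923 to 4318 elsewhere), ELF2 (4971 in IAT and 1506 to 2975 elsewhere), SLTM and CDK13 came next, and SAT had the lowest value of each of the 4.

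**Figure D3:**
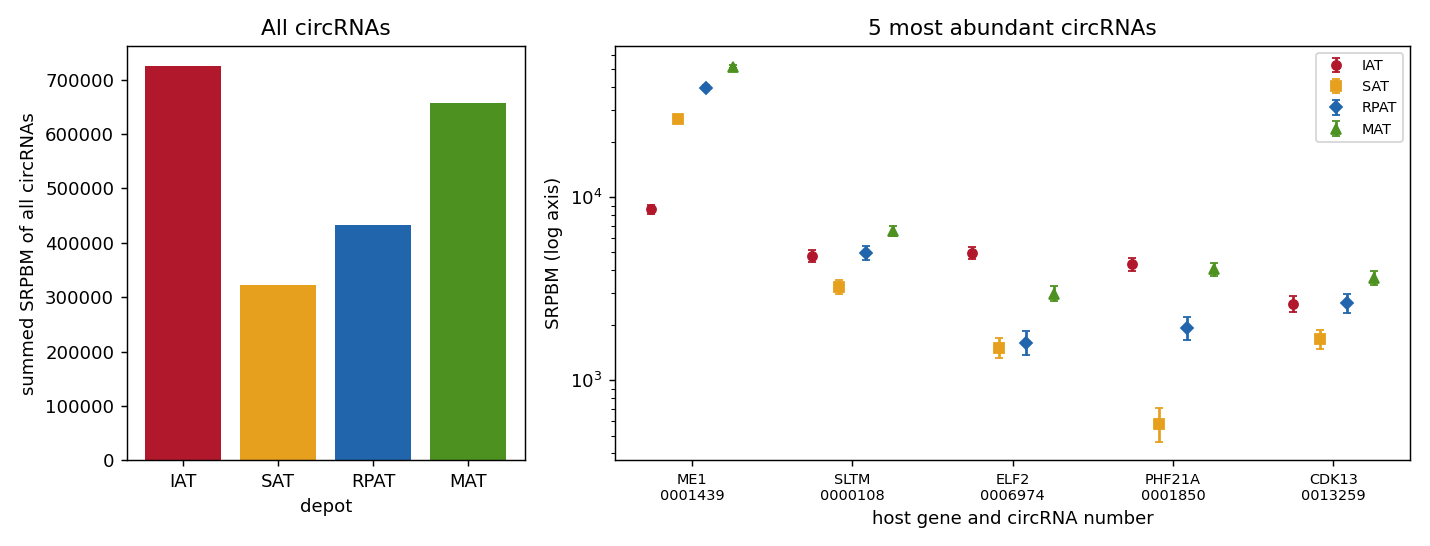
Left, summed SRPBM of all circRNAs per library as bars from 0. Right, the 5 most abundant circRNAs on a log axis by host gene, each point 1 library with the exact 95% Poisson interval of its reads; the ME1 circle runs from 8608 SRPBM in IAT to 51675 in MAT.

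The minimum of 10 reads was reached by 2318 circRNAs in IAT, 2146 in MAT, 1275 in SAT and 930 in RPAT. RPAT had the fewest mapped reads, so the minimum is strictest there. By the rule, 929 circRNAs were higher in IAT, 592 in MAT, 200 in SAT and 95 in RPAT. Simulation without change gave 14 to 21. It drew counting error alone, with no spread between animals or libraries and no difference in totals, so it is no measure of those. Taken as a share of all back-spliced reads, which removes the difference in totals, the SAT number was 402. The host gene was also higher for 106 of 874 IAT-high circRNAs with a coding host (12.1%, 10.04 to 14.5), against 9 of 1354 other IAT circRNAs of at least 10 reads (0.665%). Outside IAT it was higher for 1 of 566 in MAT, 0 of 187 in SAT (up to 1.95%) and 0 of 74 in RPAT (up to 4.86%), but few coding genes were called higher there at all (0.815%, 0.288% and 0.173%), so counts near 0 say little about hosts. Across 5114 circRNAs, Spearman's rho between the difference of a circRNA and that of its host was 0.271 in IAT and 0.133 to 0.156 in the other depots. The leading circRNAs were each found in 1 library. In IAT, ssc_circ_0009298 (chromosome 12: 55191949 to 55228102) had 340 reads, ssc_circ_0013735 had 235 and ssc_circ_0009301 had 198. In SAT, ssc_circ_0012276 and ssc_circ_0012284, both from COL3A1, had 118 and 91 reads and ssc_circ_0006119 from UBE2Q2 had 82. In RPAT, ssc_circ_0009465 from FASN had 148 reads, ssc_circ_0006299 had 70 and ssc_circ_0008994 from TEX14 had 58. In MAT, ssc_circ_0008750, ssc_circ_0009461 and ssc_circ_0012267 (COL3A1) had 44, 39 and 36 reads. No gene on the same strand spanned both ends of ssc_circ_0009298, ssc_circ_0009301, ssc_circ_0008750 or ssc_circ_0009461. Of these, ssc_circ_0009461 lies inside FASN on the opposite strand, so it is uncertain. Floors of 3 reads make the leading circRNAs at least 8.61-fold to 83.7-fold higher than in any other library.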

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

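Rows of gene classes that the comparisons did not use held reads above the limit that a count of 0 allows. The single signal recognition particle RNA row took 13.4% of the reads in SAT and 9.77% in IAT. At their highest, miRNA rows took 0.187% (IAT), misc_RNA rows 0.117% (IAT), pseudogenes 0.0666% (IAT), transcribed pseudogenes 0.0648% (RPAT), rRNA rows 0.0338% (IAT), tRNA rows 0.00227% (IAT) and the class named other 0.00206% (MAT). The 5.8S rRNA row RN5-8S stood at 88.5 FPKM in SAT, from 774 reads, and at 0.269 to 0.982 FPKM from 2 to 8 reads elsewhere. MIR6782, on the contig that also holds the 18S rRNA row, stood at 24159.5 FPKM in IAT and 12925 to 17045 elsewhere. No explanation of these values was tested.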

How the results depend on the processing

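Recomputing without the IAT library was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each depot has 1 library and no result comes from a test. The most abundant transcript of each gene was not tried because the tables hold gene rows alone. Depth limits the weak rows most: raising the read minimum or the fold lowers the counts by construction, and a pseudocount of 0.1 admits rows of few reads. All 67 depot-high or depot-low genes named by the rule kept their call with that pseudocount and under TPM, and 66 under median-ratio rescaling, where C4A in RPAT missed the threshold. Of 69 recomputed values of the list medians that the report leads with, 69 stayed on the same side of the percentiles. Of 708 recomputed values of other lists, 627 did, 41 came to lie inside the percentiles, 36 came to lie outside them and 4 changed direction. Without the muscle fibre list, Spearman's rho of IAT with the other libraries was 0.933 to 0.934, close to that with it. The list is a small part of the 20193 rows and other IAT-high genes stayed in, so rho could hardly move. It does not tell how far muscle RNA sets IAT apart.

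With a threshold of 2 log2 units, 238 genes were higher and 22 lower in IAT, 4 and 2 in SAT, 3 and 0 in RPAT, and 18 and 2 in MAT. The pairs then held 365 (IAT and SAT), 400 (IAT and RPAT), 369 (IAT and MAT), 24 (SAT and RPAT), 84 (SAT and MAT) and 44 genes (RPAT and MAT). With a pseudocount of 0.1, 504 genes were lower in IAT, 62 higher and 132 lower in SAT, 39 and 59 in RPAT, and 175 and 47 in MAT, and 647 differed between SAT and RPAT, 1213 between SAT and MAT and 638 between RPAT and MAT. LncRNAs then numbered 809 higher and 351 lower in IAT, 518 and 265 in SAT, 436 and 323 in RPAT, and 449 and 213 in MAT. A minimum of 5 FPKM left 8 genes higher in RPAT, 54 higher in MAT and 171 apart between RPAT and MAT. Median-ratio rescaling, which lowers MAT by its own construction, gave 16 genes and 4 lncRNAs lower in MAT.

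Without IAT, fewer libraries have to be passed, and 90 genes were higher and 58 lower in SAT, 40 and 7 in RPAT, and 31 lower in MAT. LncRNAs were then 57 higher and 24 lower in SAT, 2 lower in RPAT, and 34 higher and 77 lower in MAT, and circRNAs 148 higher in RPAT and 1043 in MAT. Of the list medians, 3 changed direction because the IAT value had set the comparison: muscle fibre (1.47) and glycolysis (0.27) in RPAT and smooth muscle (0.67) in MAT. By the mean over the list, progenitor and fibroblast genes in MAT went from below to above 0 (0.078), and the cause was not tested.

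CircRNAs with at least 5 reads gave 2313 higher in IAT, 648 in SAT, 468 in RPAT and 1672 in MAT. A minimum of 20 reads gave 343, 36, 21 and 154, and a 4-fold threshold 537, 106, 48 and 271. As a share of back-spliced reads, 402 were higher in SAT. With at least 40 reads, the rho between circRNA and host in RPAT was 0.22, and the cause was not tested.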

Other observations

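MAT carried RNA of plasma protein genes that the liver is known for. Other liver genes were looked up after albumin and fibrinogen had been seen to lead the MAT genes, and they did not all go the same way. Of 15 listed, 10 reached 1 FPKM in some library. Of these 10, 6 were higher in MAT than in each other library, and the median was 1.41 (100th percentile). The same 6 reached 1 FPKM in MAT alone, so MAT itself chose much of the detected set. The median and percentile are therefore no independent support. TTR reached 2.40 FPKM, HPX 3.66, AHSG 2.42 and APOC3 2.53, all under 0.2 FPKM elsewhere. SERPINC1 (1.58 against at most 0.218) and APOH (1.31 against at most 0.0525) were higher too. RBP4 (14.6 FPKM against 8.35 to 12.9), TF (7.12 against 0.301 to 5.98) and ITIH4 (2.78 against 1.78 to 4.99) did not meet the rule, and APOA1 was lowest in MAT (73.2 against 81.9 to 172). The transcription factors NKX2-3 (2.57 FPKM in MAT and at most 0.103 elsewhere) and TCF21 (1.55 and at most 0.0964), chosen after their values were seen, were also highest in MAT. In RPAT the adipokine RETN (2.30 FPKM against 0.0807 to 0.639), also chosen afterwards, was highest. On the contig of the 18S rRNA row, 2 protein-coding rows without a symbol were lowest in MAT, LOC110258600 (115 against 424 to 861 FPKM) and LOC102158401 (98.4 against 407 to 482). LOC110258600 spans the 18S rRNA row and MIR6782 on the opposite strand, so its values are uncertain.

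In the 3 patterns weighed next, the tests of dilution, of handling stress and of misjoined RNA were chosen after the result was seen, and those of read share and of temperature before. In IAT the adipocyte list had a median of -1.42 log2 units against the other depots. Loss of read share to the IAT-high genes is argued against as the whole cause. With their reads (15.1% of the IAT total) taken out, the list median was still -1.21. Muscle RNA of genes that were not IAT-high stayed in, so a larger loss of share to muscle RNA as a whole was not tested. A uniform loss of adipocytes alone would raise all other cell types alike, whereas lymphatic endothelium lay at 2.33 and blood vessel endothelium at -0.07. For a few genes, dilution of adipocyte RNA by other cells is argued against as the whole cause. Other cells can add to the RNA of a gene but not take from it. Of 41 genes of the adipocyte and synthesis lists, 6 fell at least 2-fold further in IAT than ADIPOQ, a gene of adipocytes. This held against each other library for LEP, THRSP, ACLY, ELOVL6, ME1 and ACSS2, ACLY by 3.91-fold (3.85 to 3.98). The count was 0 in SAT, RPAT and MAT. That is no control, since each was also set against IAT, where most of these genes were low. Measured from PLIN1 or CIDEC, which fell more than ADIPOQ, LEP and ACLY alone fell 2-fold further. For the rest of the 6 the answer therefore depends on the gene measured from. LEP, ACLY and THRSP were already named as far lower in IAT, and the intervals cover counting error alone. Dilution as a part of the cause remains open. Synthesis genes differed from adipocyte genes by -0.091 (bootstrap interval -0.78 to 0.37), which holds 0. The width of the interval exceeded a bound of 1 log2 unit set after the data were seen. Dilution needs 0 only if other cells express neither list, and the synthesis gene ACACB was higher in IAT. An equal fall in expression per cell would give 0 as well. For the part of the fall that these genes share, dilution and lower expression per cell therefore cannot be told apart.

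SAT had low heat shock genes and high RBM3, and lower tissue temperature under the skin, in life or after death, is a candidate explanation. Heat shock genes not named for SAT had a median of -0.64 against RPAT and MAT (percentile 0, 14 of 15 below 0), HSPA8 being at 260 FPKM against 495 and 619. With IAT included the median was -0.50 (percentile 0.01), and 0 of 15 were lower than in each other library by the rule. Against the mean of the others, the same list was high in MAT (0.41, 99.8th percentile). It lay within the middle 95% in RPAT (0.25) and IAT (-0.05). Higher levels in the abdominal depots would also lower SAT against RPAT and MAT, and this was not tested. HSPD1, HSPA9 and HSP90AB1 were lower in IAT than in SAT. DNAJB1 and HSPH1, which are named for SAT, were taken out of this list after its values were seen. CIRBP, which is also induced by cold, was 1.58-fold above RPAT (1.52 to 1.65) and 2.10-fold above MAT (2.02 to 2.18). Less handling stress was examined with the immediate early genes, which were higher in SAT by a median of 0.57 (100th percentile, 13 of 17 above 0). The list they come from had already been seen to be high in SAT, and its heat shock members went the other way. These values therefore do not decide about handling. With 1 pool per depot, an event in these animals or in sampling remains open.

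Some circRNAs with 10 or more reads in 1 library may be linear RNA of very abundant hosts misjoined in library making. Outside IAT, 30 of the 302 such circRNAs with a protein-coding host (9.93%, 6.80 to 13.9) came from hosts of at least 500 FPKM, against 15 of 2317 entries (0.647%, 0.363 to 1.07) for circRNAs found in all 4 libraries, also with coding hosts alone. Circles without a coding host, among them ssc_circ_0006299 in RPAT, were not tested. The host row of ssc_circ_0006299, MSTRG.295707, stood at 92562 FPKM in RPAT, far above the limit of 500. Among those with a coding host the share was 44.4% in RPAT (12 of 27), 15% in SAT (12 of 80) and 3.08% in MAT (6 of 195). SCD held 10, COL3A1 9 and FASN 8 of the circRNAs found in 1 library, IAT included. The intervals treat circRNAs as independent, so they are too narrow where a few hosts give many circles. Circles found in all 4 libraries count once per library. The median host FPKM was 9.46 for the 302 and 8.98 for the 2317 entries. The other 272 of the 302 came from less abundant hosts, so misjoining could account for a part alone. A depot difference in the rest was not tested.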
